A study of Saccharomyces cerevisiae with 32 samples.

How the data were processed

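Footprint and mRNA libraries were prepared from 8 budding yeast strains in 3 experiments, with 16 libraries of each assay and 2 per strain and assay. Per the labels, cells were grown to an OD600 of about 0.7, shifted in temperature and treated with cycloheximide at 100 µg/ml for 2 min before harvest, and footprints were made with RNase I. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.6.0, TopHat2 2.1.0 and DESeq2 on genome build sacCer2, without giving the role or order of each. Raw reads were not used here.

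The authors deposited 6 tables, 1 for each mutant strain against a WT, with log2 normalized levels and log2 changes per gene for footprints, mRNA and translational efficiency. Base 2 was taken from the size of the values, since the deposited tables do not state a base. Each value pools the 2 libraries of a strain and assay, and each table was scaled on its own by the authors. The deposited translational efficiency equals the deposited footprint change minus the mRNA change. Level columns were rounded by the authors, and their differences departed from the deposited changes by up to 0.147, so the deposited changes were used for every result. In the dbp1-deletion experiment the tables hold 4 WT level columns that match no sample of the series. These level columns were not used here, but the deposited changes of both strains in that experiment are against that WT.

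The tables hold 5446 reading frames, of which 5331 are in all 6 tables. By locus tag, 5444 were matched to symbols in the reference annotation and 2 were not. The reference is of another build than sacCer2, so it gave only names and neighbours, and no positions are reported. Reads of genes that overlap another transcript in the annotation, or that have near-identical copies, cannot be assigned with certainty. Copies were not searched for by sequence, so some can be unmarked.

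The comparisons were ded1-cs against DED1-CS, ded1-cs with hcDBP1 against DED1-CS and against ded1-cs, the same 3 for ded1-ts and DED1-TS, and the double mutant against the dbp1-deletion strain. These 7 comparisons, 3 differences of differences, the gene lists and the rule for named genes were set before the data were examined. The dbp1-deletion strain and the double mutant were also read against the WT of their table. A comparison of strains from different tables of an experiment is the difference of their deposited changes, in which a shared control cancels. In the dbp1-deletion experiment it was assumed and not checked that both tables share the same WT. The tests set beforehand, edgeR on counts or limma on normalized libraries, could not be run and were not run, because no value per library is in the tables. No standard deviation, standard error or p is given for this reason.

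In place of a test, a gene was counted as higher or lower when its log2 change was at least 1 in size (2-fold). Genes entered where the mean deposited level of the compared strains was at least 50 in each assay. For a difference of deposited changes, this mean was taken over the strains and controls behind both parts. In the dbp1-deletion experiment the level of that WT thus entered the mean by way of the deposited changes. The named genes are DED1 and DBP1, the 8 genes with the largest and the 8 with the smallest change in translational efficiency, and the 4 at each end for footprints and mRNA. They also include the 5 at each end of each difference of differences, up to 2 members per direction of each list, and PMA1, SFT2, GCN4, CLN3 and PAB1 in every comparison. The rule had asked for genes past the test, a raw count of 50 and list members with the smallest adjusted p, for which the 2-fold threshold, the level of 50 and the largest change stand in. A further gene named for its place in another comparison was chosen after its values were seen. Not every gene the rule picks is printed.

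The 20 gene lists fixed beforehand cover ribosomal proteins of cytosol and mitochondria, translation initiation factors, elongation and termination factors, DEAD-box helicases, mRNA decay and granule factors, glycolysis and fermentation, chaperones and general stress. They also cover ribosome biogenesis, amino acid biosynthesis under Gcn4, oxidative phosphorylation, ER translocation and glycosylation, plasma membrane transporters, cell wall mannoproteins and cyclins. Markers of a, alpha and haploid cells and auxotrophic markers complete them. A list's median is given relative to the median of all analysed genes, with its percentile among 10000 random lists matched on mean level in 20 bins. Lists with fewer than 5 members got no percentile, and a list is called outside the range below percentile 2.5 or above 97.5. These percentiles rank a list against other genes and do not replace a replicate test.

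Several choices were made after the data were seen. Random lists were first drawn from genes outside the list, and then from all analysed genes, because ribosomal protein genes fill the highest level bins. Restoration by hcDBP1 was expressed relative to the other genes, and 9 further gene lists used in the closing section were written after the first results. Added alternatives are a level minimum of 200, median centring, genes chosen in the other experiment, restoration under other scalings and filters, and random lists without the list's own genes. Those set beforehand were columns scaled to equal totals, no filter on low levels and leaving out near-identical copies.

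Overlaps are given with the number that independent lists of the same sizes would share. Correlations are across genes, which are not independent replicates. The procedure was tested on simulated data, in which genes varied independently of each other and of their level. Lists of 200 genes shifted by a log2 of 1 and 2 gave medians of 1.04 and 1.95 for ded1-cs and 1.07 and 2.04 for ded1-ts. Of 400 unshifted lists of 30 genes, 14 lay outside the range for ded1-cs and 27 for ded1-ts, and this number of lists was raised after a first smaller run. How often lists of genes that vary together fall outside the range was not simulated. Depth per library is unknown, and the normalized levels, which are not read counts, give no counting error. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.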

Results

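Ribosome footprints and mRNA were sequenced from budding yeast strains altered in DED1 and DBP1, genes for related DEAD-box RNA helicases. Ded1 is known to act in the initiation of translation. The 32 libraries, 16 of footprints and 16 of mRNA, came from 8 strains with 2 libraries per strain and assay. The experiment at 15 °C held a DED1-CS strain, its cold-sensitive mutant ded1-cs, and ded1-cs with high-copy DBP1 (hcDBP1). The experiment on heat sensitivity at 37 °C held DED1-TS, ded1-ts and ded1-ts with hcDBP1. A further experiment at 37 °C held a dbp1-deletion strain and a ded1-ts dbp1-deletion double mutant. The authors deposited 1 pooled log2 level per gene, strain and assay, and log2 changes against the WT of each table. No spread between replicates can therefore be given, and no difference reported here was tested against one. Sequencing depth is unknown, and the deposited normalized levels summed to between 5651054 and 48359134 per strain and assay in their columns. Translational efficiency is the log2 footprint change minus the log2 mRNA change. A gene is counted as higher or lower where its log2 change is at least 1 in size, among genes with a mean level of at least 50 in each assay.

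DED1 (YOR204W) and DBP1 (YPL119C) themselves differed between strains. In the authors' deposited table, DED1 footprints in ded1-cs stood at 2.72 (log2) above DED1-CS and DED1 mRNA at 1.37. In ded1-ts the authors' deposited table gives DED1 at -0.99 in footprints and -1.17 in mRNA. In the double mutant DED1 stood at 1.09 in footprints and 1.67 in mRNA against the dbp1-deletion strain by difference of the deposited changes. The dbp1-deletion strain itself had DED1 at -1.46 in footprints and -2.63 in mRNA against its WT in the authors' deposited table. DED1 mRNA in the double mutant also stood below that WT, so the positive values do not show DED1 raised over WT. High-copy DBP1 had DBP1 footprints of 5.41 and mRNA of 5.85 over the control at 15 °C in the authors' deposited table. At 37 °C the authors' deposited table gives 4.66 for DBP1 footprints and 6.89 for DBP1 mRNA in the hcDBP1 strain, a translational efficiency of -2.24. Without hcDBP1, DBP1 mRNA in ded1-ts stood at 1.33 over DED1-TS in the authors' deposited table. In the dbp1-deletion strain the deposited log2 level of DBP1 was -0.17 in mRNA and 0.51 in footprints, and in the double mutant -3.55 and -1.33.

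The comparison of ded1-cs with DED1-CS at 15 °C asks which mRNAs are translated differently when Ded1 function is impaired in the cold. Genes for plasma membrane transporters and cyclins stood far lower in translational efficiency, while chaperone genes stood higher. The respiratory chain list also had a higher median, with lower mRNA and with footprints inside the range of random lists. In the authors' deposited table, PMA1, the plasma membrane proton pump, stood at -2.81 (log2), ZRT2, a zinc transporter, at -3.00 and FET3, an iron uptake oxidase, at -2.96. CLB2 and CLB1, the mitotic cyclins, stood at -3.12 and -2.81 in the authors' deposited table, and the G1 cyclin CLN3 at -1.42. PAB1, the poly(A) binding protein, stood at -1.70 and SFT2, a Golgi traffic protein, at -2.76 in the authors' deposited table. At the other end, the authors' deposited table lists SSA3, an Hsp70 chaperone, at 3.43 and BTN2, a sorting factor for misfolded proteins, at 2.91.

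Relative to all genes, the transporter list had a median translational efficiency of -1.07, at percentile 0 of random lists of the same level, with 17 of 35 members lower and 1, the glucose transporter HXT3, higher. Cyclins and G1 regulators had a median of -1.28 relative to all genes (percentile 0.455), with 10 of 17 members lower and 0 higher. Heat shock proteins and chaperones stood at 0.79 (percentile 99.6), with 13 of 27 members higher and 1 lower. Oxidative phosphorylation genes stood at 0.67 (percentile 99.99), with 11 of 34 higher, among them QCR7 of complex III at 1.52 and cytochrome c CYC1 at 1.45 in the authors' deposited table. Their mRNA median was -0.20 (percentile 0.54) and their footprint median 0.29, inside the range of random lists. The 5 lower members of that list included the F1 ATPase subunits ATP2 and ATP1, at -3.23 and -2.19 in the authors' deposited table. Ribosomal protein genes stood at 0.57 relative to all genes, inside the range of random lists of the same high level (percentile 55.6), with 21 of 136 higher and 0 lower.

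The lowest translational efficiencies of single genes lay in varied functions. In the authors' deposited table these were PDE2, the high-affinity cAMP phosphodiesterase, at -4.12, IRC23 at -3.96, the RNA polymerase II subunit RPB7 at -3.86 and the mitochondrial nucleotide carrier RIM2 at -3.85. YMR1, a phosphoinositide phosphatase, stood at -3.67, the kinetochore-associated SLK19 at -3.63, and EFR3 and the mitochondrial peptidase IMP1 each at -3.49 in the authors' deposited table. The highest after SSA3 in the authors' deposited table were BSC1 at 3.26, YNL042W-B at 3.15, RPL41A at 2.99 and RPL41B at 2.97, YDR222W at 2.90 and the cell wall protein DAN4 at 2.75. RPL41A and RPL41B are near-identical copies and YNL042W-B overlaps a noncoding RNA gene, so the reads of these 3 cannot be assigned with certainty.

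Heat shock genes also stood higher in mRNA. The chaperone list had a median mRNA change of 0.71 relative to all genes (percentile 100, 8 of 27 members higher), and a median footprint change of 1.65 with 18 of 27 higher. Footprints in the authors' deposited table stood at 6.09 for BTN2, 5.33 for the plasma membrane heat shock protein HSP30, 4.41 for ROQ1 and 4.02 for the Hsp70 gene SSA4. Glycolysis and fermentation genes had a median footprint change of 1.01 relative to all genes (percentile 100), with 10 of 17 higher and 1 lower. Ribosome biogenesis genes stood at -0.46 in mRNA (percentile 0) and amino acid biosynthesis genes under Gcn4 at -0.32 (percentile 0.02). The lowest mRNA changes in the authors' deposited table were YEL073C at -2.42, IZH4, a membrane protein, at -2.31 and ARG3 of arginine synthesis at -2.12, and the highest beside BTN2 was POX1, the peroxisomal acyl-CoA oxidase, at 2.41.

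In all, 832 of 5076 genes were higher and 1113 lower in translational efficiency in ded1-cs, 709 higher and 1023 lower in footprints, and 62 higher and 45 lower in mRNA. Scaling the columns to equal totals shifts every gene's translational efficiency by -0.59 and gives 91 higher and 1789 lower, with 157 and 1663 in footprints and 86 and 38 in mRNA. List medians relative to all genes are free of that shift, and the counts of list members are as deposited. Under that shift fewer list members would count as higher and more as lower. The oxidative phosphorylation genes QCR7 and CYC1, for example, fall below 2-fold.

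The comparison of ded1-ts with DED1-TS at 37 °C puts the same question in the heat. Plasma membrane transporter and cell wall genes stood lower in translational efficiency and ribosomal protein genes higher, the latter with lower mRNA and not with more footprints, and most of the lowest single genes lay outside these lists. In the authors' deposited table, RSP5, an essential ubiquitin ligase, stood at -3.24, RPO31, the largest subunit of RNA polymerase III, at -3.20, REG1, a phosphatase regulator of glucose repression, at -3.11 and SEC7, an exchange factor of the Golgi, at -3.03. LEC1 stood at -2.91, the nuclear ubiquitin ligase SAN1 at -2.87, the mitochondrial protease YTA12 at -2.79 and the glucan synthase FKS1 at -2.78 in the authors' deposited table. Higher genes in the authors' deposited table included the urea transporter DUR3 at 2.47, SSA3 at 1.46 and GCN4, the activator of amino acid synthesis, at 1.43.

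The ribosomal protein list stood at 0.48 relative to all genes (percentile 100), with 8 of 136 members higher and 1 lower. Its mRNA median was -0.56 (percentile 0) and its footprint median -0.05, so its higher translational efficiency went with lower mRNA. The lower member is RPL22B, at -2.30 in the authors' deposited table. Genes of ER translocation and glycosylation stood at 0.28 (percentile 99.97), with mRNA at -0.34 (percentile 0.5) and footprints at -0.08. Only 2 of 32 passed 2-fold, the translocon subunit SSS1 at 1.06 and the signal peptidase subunit SPC3 at 1.13 in the authors' deposited table. Plasma membrane transporters stood at -0.41 (percentile 0.02), with 7 of 34 lower, among them the drug pump SNQ2 at -2.48, the ammonium permease MEP3 at -1.86 and PMA1 at -1.19 in the authors' deposited table. Cell wall genes stood at -0.26 (percentile 0.13) with 5 of 30 lower, including the chitin synthase CHS3 at -1.81 in the authors' deposited table. Oxidative phosphorylation genes stood at 0.12 relative to all genes (percentile 99.4), although the authors' deposited table has ATP1 at -1.66 and ATP2 at -1.60. Initiation factors SUI1 and TIF11 stood at 1.35 and 1.14 in the authors' deposited table, and PAB1, of the same list, at -1.27. CLN3 stood at -0.85 and SFT2 at -0.77 in the authors' deposited table, while the decay exonuclease XRN1 stood at -2.55 and the granule protein PBP1 at -1.93.

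In mRNA, cyclins and G1 regulators stood at -0.58 relative to all genes (percentile 0) with 6 of 17 lower, and in footprints at -1.10 with 9 of 17 lower. Their translational efficiency median was -0.39 (percentile 0.995), with CLB2 at -2.13 in the authors' deposited table. Chaperone mRNA stood at 0.30 (percentile 100) with 6 of 27 members higher. The lowest mRNA values in the authors' deposited table were the cell wall mannoprotein CWP1 at -4.32, the mating-type endonuclease HO at -3.78, the aldehyde dehydrogenase ALD6 at -2.86 and FET3 at -2.66. The highest were ECM13 at 3.29, NCA3 at 2.80, MOH1 at 2.79 and POX1 at 2.54 in the authors' deposited table.

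Over 5222 genes, 149 were higher and 333 lower in translational efficiency in ded1-ts, with 349 and 347 in footprints and 216 and 167 in mRNA. With columns scaled to equal totals, the split was 472 higher and 278 lower in footprints and 400 and 96 in mRNA. YGL193C and YNL042W-B, at 3.48 and 2.62 in the authors' deposited table, overlap other transcripts, and RPL41A, at 2.48 there, has a near-identical copy.

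The mutants at 15 °C and 37 °C share no library, so their lists can be set side by side. Of 330 genes lower in translational efficiency in ded1-ts, 270 (81.8%) were also lower in ded1-cs, where independent lists would share 72.2. Among them are RSP5, FKS1, CLB2, ATP1, ATP2 and PMA1. Of 120 genes higher in ded1-ts, 57 were higher in ded1-cs against 19.7 for independent lists, SSA3, SUI1 and TIF11 among them. Only 4 genes were lower in ded1-cs and higher in ded1-ts, and 0 the reverse. Across 5068 genes Pearson's r was 0.60 and Spearman's rho 0.55. Genes are not independent replicates, so these overlaps and correlations carry no p.

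GCN4 was the highest gene in the difference, ded1-ts effect minus ded1-cs effect, at 3.83, since the authors' deposited table has it at -2.40 in ded1-cs and 1.43 in ded1-ts. PHO84, the phosphate transporter, followed at 3.73, although it overlaps a noncoding RNA gene, then MIN6 at 3.62, IRC23 at 3.60 and the kinetochore gene AME1 at 3.50. YER053C-A had the lowest difference, -7.35, but it lay below the level minimum in the ded1-cs comparison and its mean footprint level over the 4 strains was 52.5. Other low differences were -2.64 for YDR222W, -2.55 for BTN2, -2.54 for RPL22B and -2.48 for HO. By list, cyclins and G1 regulators stood at 0.98 in this difference relative to all genes (percentile 99.79) and transporters at 0.39 (percentile 99.75). The cyclin list differed by -0.84 in mRNA (percentile 0) and by 0.15 in footprints, inside the range. Cell wall genes stood at -0.82 (percentile 0.01) and chaperones at -0.72 (percentile 0.1). Of 5167 genes, 869 differed upward and 496 downward, or 1625 and 70 with columns scaled to equal totals, and the difference between the mutants was not tested.

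**Figure D1:**
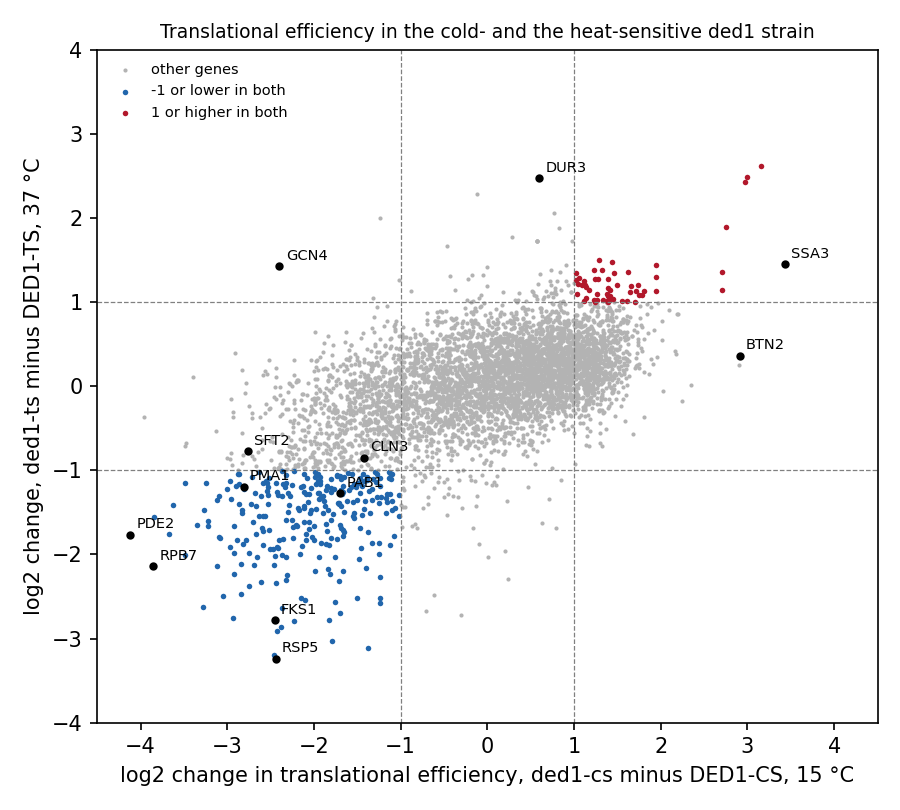
Log2 change in translational efficiency in ded1-cs against DED1-CS at 15 °C (horizontal axis) and in ded1-ts against DED1-TS at 37 °C (vertical axis), 1 point per gene for 5068 genes. Points lower in both mutants (270 genes) and higher in both (57 genes) are coloured, and the lower left corner holds many more genes than the corners of opposite sign, which hold 4 and 0.

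High-copy DBP1 was introduced to ask whether it restores translation in ded1-cs. Against ded1-cs, hcDBP1 went with higher translational efficiency for several genes that stood lowest in the mutant. By difference of the deposited changes, YMR1 stood at 2.07, IRC23 at 2.01, FET3 at 1.97 and RIM2 at 1.74. MCO6, of mean footprint level 50.9, at 1.71, YTP1 at 1.70, the mitochondrial ribosomal protein MRP7 at 1.61 and the oligosaccharyltransferase subunit OST1 at 1.19 were also higher. MRP51, at 1.68, is the neighbour of DBP1 and its mRNA stood at 0.72, so its value cannot be separated from the altered locus. YNL042W-B, the overlapping gene, had the highest value at 2.29. PMA1 stood at 0.93, SFT2 at 1.01, GCN4 at 0.75, CLN3 at 0.45 and PAB1 at 0.37.

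Of the lists that stood low in ded1-cs, transporters stood at 0.16 relative to all genes (percentile 99.9), with 1 of 35 past 2-fold, and cyclins at 0.43 (percentile 99.85), with 0 of 17. The ded1-cs libraries enter both their low values and this difference, which by itself favours values above 0. Cell wall genes stood at -0.31 (percentile 0), oxidative phosphorylation genes at -0.19 (percentile 0.09) and a mating type markers at -0.32 (percentile 0.95). Relative to all genes these lists had medians of 0.65, 0.67 and 0.70 in ded1-cs. For them the shared libraries by themselves favour values below 0. Among the lowest genes were SNG1 at -1.20, the sulfonate dioxygenase JLP1 at -1.13, YDR222W at -1.11 and the flocculin FLO11 at -1.07. Chaperone mRNA had a median of -0.65 relative to all genes (percentile 0), with 8 of 27 members lower, and general stress mRNA one of -0.37 (percentile 0). The mRNA of BTN2 stood at -2.65, of TMA10 at -1.87, of ROQ1 at -1.86 and of the carbonic anhydrase NCE103 at -1.55, while BSC1 at 1.34 and PRM7 at 1.20 were higher. HSP30 footprints stood at -2.17.

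Of 5077 genes, 108 were higher and 12 lower in translational efficiency with hcDBP1 than without at 15 °C, 153 and 45 in footprints, and 3 and 15 in mRNA. Equal column totals shift every gene by 0.17 and give 210 higher and 1 lower in translational efficiency, with 239 and 30 in footprints. Against DED1-CS, the hcDBP1 strain had 467 higher and 666 lower of 5072 genes in translational efficiency, 294 and 557 in footprints and 29 and 44 in mRNA. Equal column totals give 86 and 1230 there in translational efficiency and 56 and 1039 in footprints, and median centring 300 and 818, with 177 and 675 in footprints.

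Genes still low with hcDBP1 at 15 °C in the authors' deposited table included PDE2 at -3.03, PAM1 at -2.47, the Golgi guanosine diphosphatase GDA1 at -2.42, YML018C at -2.40, CLB1 at -2.36, ATP2 at -2.34 and ZRT2 at -2.22. BTN2 at 2.75 and SSA3 at 2.53 stood high there in the authors' deposited table, as did the uncertain YNL042W-B at 5.45 and RPL41A at 3.85. Against DED1-CS, transporters stood at -0.88 relative to all genes (percentile 0), cyclins at -0.81 (percentile 0.89) and chaperones at 0.69 (percentile 99.99).

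In ded1-ts at 37 °C the same question was asked of hcDBP1. Cell wall genes stood higher in translational efficiency than in ded1-ts alone. The GTPase gene RHO2 stood at 1.78, RPB7 at 1.76, HO at 1.71, CWP1 at 1.68, RPO31 at 1.67, the mRNA export factor YRA1 at 1.63 and APD1 at 1.52. IMD4 of GTP synthesis, at 1.72, overlaps another transcript. FKS1 stood at 1.42, RPL22B at 1.33, PBP1 at 1.20, SNQ2 at 1.10, ATP1 at 1.02 and ATP2 at 1.00, all lower in ded1-ts. PAB1 stood at 0.90, PMA1 at 0.68, SFT2 at 0.52, CLN3 at 0.33 and GCN4 at -0.30.

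Cell wall genes had a median of 0.40 relative to all genes (percentile 100), with 7 of 30 higher. Glycolysis genes stood at 0.25 (percentile 99.3) and mitochondrial ribosomal protein genes at 0.10 (percentile 99.95). ER translocation genes stood at -0.09 (percentile 0.73) and ribosomal protein genes at -0.02 (percentile 0). In ded1-ts against DED1-TS, cell wall genes stood at -0.26, ER translocation genes at 0.28 and ribosomal protein genes at 0.48. The ded1-ts libraries enter both sets of values, which by itself favours opposite signs. The lowest genes were DBP1 itself at -2.27, the mitochondrially encoded COX3 at -1.53, YOR192C-C at -1.47 and FLO11 at -1.46. In mRNA, cyclins and G1 regulators stood at 0.62 (percentile 100), with 4 of 17 higher. CWP1 stood at 3.95 in footprints and 2.27 in mRNA.

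Of 5214 genes, 67 were higher and 16 lower in translational efficiency with hcDBP1 than without at 37 °C, 121 and 30 in footprints, and 36 and 17 in mRNA. Equal column totals give 43 and 23 in translational efficiency and 85 and 94 in footprints. Against DED1-TS, 46 of 5208 genes were higher and 155 lower in translational efficiency, 97 and 55 in footprints and 88 and 31 in mRNA. Equal column totals give 19 and 296, with 73 and 63 in footprints and 187 and 22 in mRNA, and median centring gives 28 and 214. Genes still low there in the authors' deposited table included the alcohol acetyltransferase ATF1 at -2.53, LST4 at -2.24, SEC7 at -2.03, REG1 at -2.01, XRN1 at -1.84 and FKS1 at -1.37. Part of this was higher mRNA for REG1, SEC7 and XRN1, at 1.03, 0.64 and 0.69 in the authors' deposited table. Their footprints stood at -0.97, -1.39 and -1.14, and those of ATF1, LST4 and FKS1 at -2.52, -2.11 and -1.17. Across the 5208 genes, r between the changes in mRNA and translational efficiency was -0.62, and mRNA is subtracted in the latter. DUR3 stood at 1.84 in the authors' deposited table, and the copies RPL41A and RPL41B at 2.24.

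To keep the choice of genes apart from the libraries in which restoration is read, genes lowered in the mutant of the other experiment were followed. The 330 genes lower in ded1-ts had a median translational efficiency of -1.83 in ded1-cs and -1.39 in ded1-cs with hcDBP1. Their difference between hcDBP1 and ded1-cs had a median of 0.49, against 0.03 for the other genes, and 88.8% of them stood above 0. Genes lower in ded1-cs stood less low in ded1-ts, at a median of -0.49 with 24.3% of 1109 lower by 2-fold. With hcDBP1 they stood at -0.31 against DED1-TS. The 1108 genes lower in ded1-cs had a median of 0.18 for hcDBP1 in ded1-ts, against -0.02 for the other genes, with 70.8% above 0. The medians of 0.49 and 0.18 lay at percentile 100 of random lists. Genes chosen in the same experiment gave 0.53 at 15 °C and 0.59 at 37 °C, where the mutant library enters both the choice of genes and the difference. Genes higher in the mutant of the other experiment stood slightly lower with hcDBP1. The 119 higher in ded1-ts had a median of -0.08 for hcDBP1 in ded1-cs, against 0.05 for the other genes (percentile 0.1). The 831 higher in ded1-cs had -0.06 for hcDBP1 in ded1-ts, against 0.03 (percentile 0).

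Of 1110 genes lower in ded1-cs, 456 (41.1%) were no longer lower by that measure against DED1-CS with hcDBP1, and of 333 lower in ded1-ts, 202 (60.7%), with each pair of comparisons sharing its control libraries. Genes chosen at a threshold can cross it again without restoration, and how many would do so is not known. Lower only with hcDBP1 were 10 genes at 15 °C and 21 at 37 °C. Genes higher with hcDBP1 at both temperatures numbered 5 of 107 and 66, against 1.39 for independent lists, with r at 0.19 across genes. Of 65 genes higher with hcDBP1 in ded1-ts, 50 were lower in ded1-cs, against 14.2 for independent lists. The hcDBP1 effect at 37 °C minus that at 15 °C was highest for genes such as the sulfiredoxin gene SRX1 at 2.08. The S-methylmethionine permease MMP1 stood at 1.78, the cold-shock mannoprotein TIR1 at 1.75 and HO at 1.67. For SRX1 the difference lay in mRNA, at -1.94, with footprints at 0.14. MMP1, TIR1 and HO differed in footprints by 1.77, 1.64 and 3.41. Genes low in the difference of hcDBP1 effects included YNL042W-B at -3.37, PHO84 at -3.27, RRT13 at -2.58 and MCO6 at -2.43. Of these, YNL042W-B and PHO84 overlap noncoding RNA genes. Cell wall genes stood at 0.69 relative to all genes in that difference (percentile 100) and cyclins at -0.39 (percentile 0.13), the cyclins with mRNA at 0.54 (percentile 100) and footprints at 0.10. Over 5160 genes, 66 differed upward and 133 downward, or 21 and 455 with equal column totals, and this difference was not tested either.

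**Figure D2:**
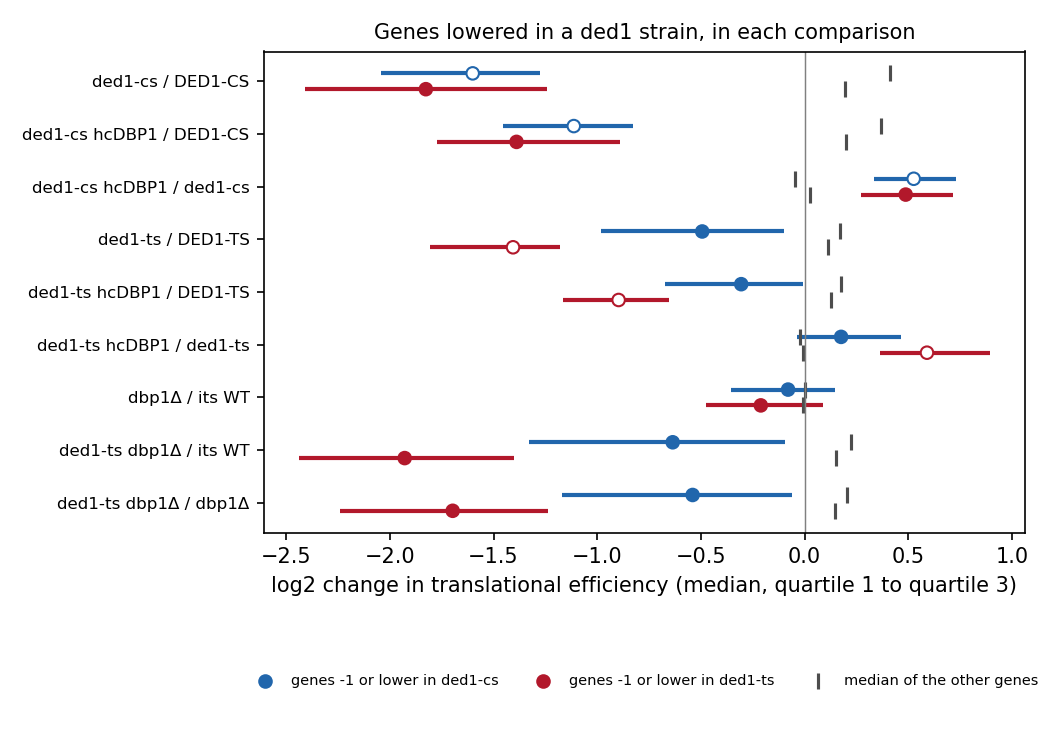
Median log2 change in translational efficiency, with bars from the first to the third quartile, of the genes lower in ded1-cs and of the genes lower in ded1-ts, in each comparison. Filled circles mark comparisons that share no library with the choice of genes, open circles those that do, and grey ticks the median of the other genes. The genes lower in ded1-ts stand at -1.83 in ded1-cs and at -1.70 in the double mutant against the dbp1-deletion strain.

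The dbp1-deletion strain was compared with the WT of its own table, which matches no sample of the series. LEU1, BAT1 and other genes of amino acid synthesis stood high in mRNA, and general stress genes stood low in translational efficiency with higher mRNA. In the authors' deposited table LEU1 of leucine synthesis stood at 4.46 in mRNA, the transaminase BAT1 at 2.96, the carrier OAC1 at 2.85 and the drug exporter QDR2 at 2.65. The lowest mRNA values in the authors' deposited table, after DBP1 at -6.21, were HIS3 of histidine synthesis at -3.74, the serine deaminase CHA1 at -2.86 and DED1 at -2.63. In translational efficiency the authors' deposited table has the peroxisomal citrate synthase CIT2 at 1.92, DLD3 at 1.89, PDH1 at 1.88 and the amino acid permease DIP5 at 1.17. YAR068W, of mean footprint level 52.4, stood at -3.08, GAC1 at -2.20, PHM7 at -1.88, CIP1 at -1.87, MRP51, next to the deleted gene, at -1.84, CWP1 at -1.79 and TSL1 of trehalose synthesis at -1.74 in the authors' deposited table. There PHM7, CIP1 and TSL1 had mRNA at 2.44, 2.11 and 2.01 with footprints at 0.56, 0.24 and 0.27, so their footprints did not fall. GAC1 and CWP1 had mRNA at 1.57 and 1.62 with footprints at -0.63 and -0.17. YAR068W had mRNA at 1.92 and footprints at -1.16, and MRP51 had -0.31 and -2.15. In translational efficiency the authors' deposited table has GCN4 at 1.10, SFT2 at 0.06, PMA1 at -0.31 and PAB1 at -0.69. CLN3 stood at -1.39 there, with mRNA at 1.64 and footprints at 0.24. Across 4971 genes, r between the changes in mRNA and translational efficiency was -0.70, and mRNA is subtracted in the latter.

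General stress genes stood at -0.77 in translational efficiency relative to all genes (percentile 0), with 8 of 23 lower, and at 0.69 in mRNA (percentile 100), with footprints at -0.06, inside the range. Ribosome biogenesis genes stood at 0.37 in translational efficiency (percentile 100) and -0.56 in mRNA (percentile 0), with footprints at -0.21 (percentile 0). Amino acid biosynthesis genes under Gcn4 stood at 0.68 in mRNA (percentile 100), with 14 of 45 higher and 1 lower. Of 4971 genes, 19 were higher and 91 lower in translational efficiency, 65 and 31 in footprints, and 214 and 65 in mRNA. Equal column totals give 53 and 53 in translational efficiency and 154 and 124 in mRNA.

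The double mutant was compared with the dbp1-deletion strain to ask what ded1-ts does when DBP1 is absent. The comparison assumes that the tables of both strains share the same WT. REG1, RPO31, RSP5 and FKS1, among the lowest in ded1-ts, stood low here too. By difference of the deposited changes, the pH-sensing protein RIM21 stood at -4.65, REG1 at -4.11, the stress kinase SSK2 at -4.04, the cell wall integrity kinase PKC1 at -3.87, RPO31 at -3.69, APD1 at -3.64, ATF1 at -3.58 and RSP5 at -3.44. FKS1 stood at -3.16, XRN1 at -2.88, SNQ2 at -2.61, MEP3 at -2.56, PBP1 at -2.32, CHS3 at -2.21, ATP1 at -2.06 and CLB2 at -1.88. PMA1 stood at -1.85, PAB1 at -1.36, SFT2 at -0.71 and CLN3 at -0.45, with GCN4 at 0.65. SSA3 stood highest at 3.39, then DUR3 at 2.69, YNR014W at 2.04 and YNL194C at 1.96, and among list members the zinc transporter ZRT1 stood at 1.49 and the elongation factor EFT2, which has a near-identical copy, at 1.52.

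General stress genes stood at 0.40 relative to all genes (percentile 99.96) with footprints at 0.33 (percentile 99.5), and 4 of 23 were higher in translational efficiency. Against the WT of the table the same list stood at -0.38 in translational efficiency in the double mutant (percentile 0.895), with 5 of 23 lower and 0 higher, and the dbp1-deletion strain itself stood at -0.77. The cell wall list stood at 0.45 (percentile 99.8), but at -0.65 in mRNA (percentile 0, 9 of 27 lower) and -0.55 in footprints (percentile 0.06), with 10 of 27 lower and 2 higher. ER translocation genes stood at 0.34 (percentile 99.98) with 2 of 32 higher, and their mRNA stood at -0.31 (percentile 0.5) and their footprints at -0.06, inside the range. Transporters stood at -0.18 (percentile 1.79) and mitochondrial ribosomal protein genes at -0.20 (percentile 0.49). In mRNA, cyclins and G1 regulators stood at -0.67 (percentile 0), with 8 of 17 lower, and chaperones at 0.50 (percentile 100). The mRNA of CWP1 stood at -5.06, of the S-phase cyclin CLB6 at -4.40, of HO at -3.98 and of ALD6 at -3.91, with DGR2 at 4.60 and MOH1 at 3.04 above. Of 4983 genes, 109 were higher and 412 lower in translational efficiency, 338 and 426 in footprints, and 173 and 182 in mRNA. Equal column totals shift every gene by -0.20 and give 48 and 528, with 260 and 513 in footprints and 230 and 154 in mRNA.

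Against the WT of its table, the double mutant had 130 of 5007 genes higher and 515 lower in translational efficiency, 452 and 448 in footprints, and 497 and 248 in mRNA. Equal column totals give 370 and 523 in footprints. RSP5 stood at -4.32, SSK2 at -4.25, REG1 at -4.18, PKC1 at -4.12, FKS1 at -3.94, the corepressor SIN3 at -3.90, the lipid flippase DNF2 at -3.88 and the mRNA-binding SSD1 at -3.85 in the authors' deposited table. The mRNA of PCL5, a cyclin that acts on Gcn4, stood at 3.73 and of SNO1 at 3.47, while HO stood at -4.47, HIS3 at -3.92, the histone gene HTA2, which has a close copy, at -3.80 and PCL1 at -3.70 in the authors' deposited table.

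Genes lower in ded1-ts and in the double mutant against the dbp1-deletion strain numbered 281 of 325 and 412, where independent lists would share 26.9, and r across genes was 0.83. The 325 genes had a median of -1.70 in the double mutant comparison. Genes lower in the double mutant and higher with hcDBP1 in ded1-ts numbered 53 of 64, against 5.29 for independent lists. The ded1-ts effect without DBP1 minus that with DBP1 was at least 1 in size for 113 of 5123 genes, 35 upward and 78 downward, or 20 and 126 with equal column totals. The effects with and without DBP1 come from different experiments with different control strains. Absence of DBP1 cannot be told apart from these in the difference. Genes high in it included DAN4 at 4.30, YHR033W at 3.40, SSA3 at 1.93 and the siderophore transporter ENB1 at 1.69. The mean footprint levels of DAN4 and YHR033W were 50.6 and 52.2, close to the minimum of 50. Genes low in it were RPL41B at -2.51, a near-identical copy of RPL41A, YOR192C-C and the alpha agglutinin gene SAG1, of mean footprint level 54.6, at -2.16, and RIM21 at -2.08. Cell wall genes stood at 0.50 and general stress genes at 0.41 in this difference relative to all genes, both at percentile 100. Of 18 lists, 4 lay above the range and 2 below. Those below were cytosolic ribosomal protein genes at -0.13 (percentile 0) and mitochondrial ribosomal protein genes at -0.23 (percentile 0.135). The difference between the ded1-ts effects was not tested. DED1 itself differed by 2.84 in mRNA and 2.08 in footprints between these effects. The general stress list differed in footprints, at 0.44 (percentile 100), with mRNA at 0.00, and the cell wall list in mRNA, at -0.39 (percentile 0), with footprints at 0.11, inside the range.

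The other lists fixed before the data were examined lay inside the range of random lists in translational efficiency in ded1-cs. Relative to all genes, mitochondrial ribosomal protein genes stood at 0.20, translation initiation factors at 0.41, elongation and termination factors at 0.42, DEAD-box helicases at 0.03 and mRNA decay and granule factors at 0.13. Glycolysis genes stood at 0.81, general stress genes at 0.19, ribosome biogenesis genes at 0.27, amino acid biosynthesis genes under Gcn4 at 0.34, ER translocation genes at -0.33 and cell wall genes at 0.65. Of the strain markers, a mating type genes stood at 0.70 and haploid genes at 0.52, both inside the range, while the 2 alpha mating type genes at 0.37 and the 4 auxotrophic marker genes at -0.15 were too few for a percentile. Outside the range in translational efficiency lay 4 of 18 lists in ded1-cs, 5 of 18 with hcDBP1 against ded1-cs, 6 of 19 in ded1-ts, 5 of 19 with hcDBP1 against ded1-ts and 7 of 18 in the double mutant against the dbp1-deletion strain.

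**Figure D3:**
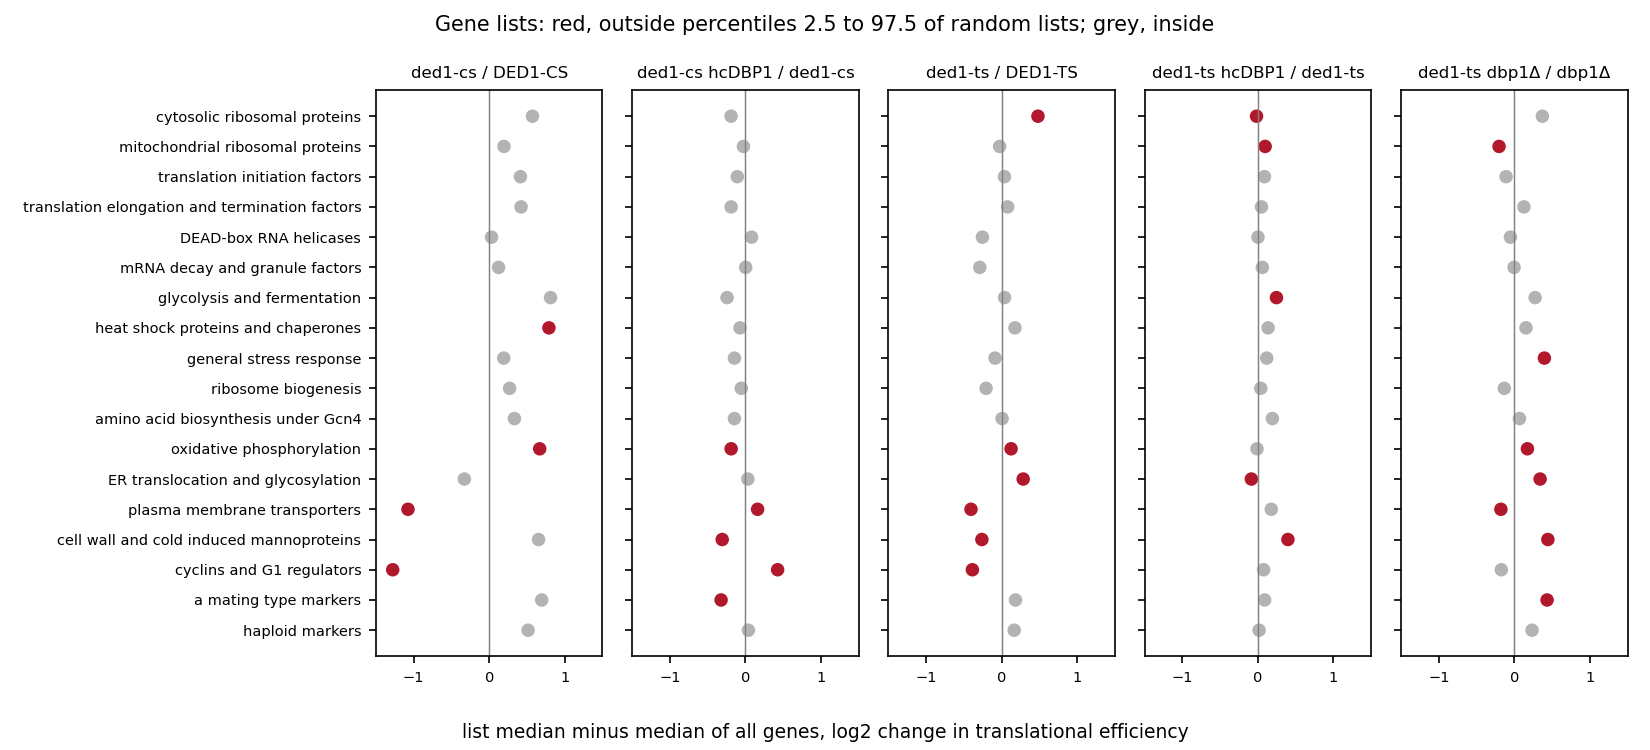
Median log2 change in translational efficiency of each gene list relative to all genes, in 5 comparisons. Red marks lists outside percentiles 2.5 to 97.5 of random lists of the same level, such as plasma membrane transporters at -1.07 and cyclins at -1.28 in ded1-cs.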

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

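The level minimum of 200, median centring, genes chosen in the other experiment and random lists without their own genes were chosen after the data were seen, and the other alternatives beforehand. No paired analysis was possible because the tables hold 1 pooled value per strain and assay. For the same reason DESeq2 size factors, TMM within assays, the DESeq2 Wald test, fits on 2 strains only, replicate terms, leaving out each library, estimated correlations, gene choice by replicate and a simulated shared control were not run. Depth per library is unknown, so its effect cannot be given. The majority of some splits turned. With columns scaled to equal totals, footprints for hcDBP1 against ded1-ts went from 121 higher and 30 lower to 85 and 94, and footprints of the double mutant against the WT from 452 and 448 to 370 and 523. Its mRNA against the dbp1-deletion strain went from 173 and 182 to 230 and 154, and translational efficiency in the dbp1-deletion strain from 19 and 91 to 53 and 53. Footprints in ded1-ts went from 349 and 347 to 321 and 371 with median centring and to 259 and 324 at a level of 200, where those of the double mutant against the WT were 284 and 328. Without a level filter the double mutant against the dbp1-deletion strain gave 512 and 460 in footprints, against 338 and 426, and 254 and 210 in mRNA, and the dbp1-deletion strain gave 88 and 132 in footprints, against 65 and 31. The cause was not tested. Results were called the same when counts of higher and lower genes together stayed within 1.5 times, or restoration medians within 0.1, of the one reported. This does not see a changed split by direction. Translational efficiency in ded1-cs, for one, is called the same although it went from 832 higher and 1113 lower to 91 and 1789 under equal totals. Results called the same numbered 31 of 35 with columns scaled to equal totals and 35 of 35 with median centring. They numbered 35 of 42 without a level filter and 38 of 42 at a level of 200. Of named genes, 58 of 300 under equal totals and 14 of 300 under median centring ended below 2-fold.

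Without a level filter more genes enter, and the counts for hcDBP1 against ded1-cs became 304 in footprints and 215 in translational efficiency. Those for hcDBP1 against ded1-ts became 232 and 149, those for the dbp1-deletion strain 220 and 238, and that for the ded1-ts effect without minus with DBP1 191. At a level of 200 fewer genes enter, and translational efficiency counts were 78 for hcDBP1 against ded1-cs, 71 for the dbp1-deletion strain, 65 for the ded1-ts effect without minus with DBP1 and 132 for the hcDBP1 effect at 37 °C minus 15 °C. Under equal totals the counts were 211 for hcDBP1 against ded1-cs in translational efficiency, 209 in mRNA and 315 in translational efficiency for hcDBP1 in ded1-ts against DED1-TS, and 476 for the hcDBP1 effect at 37 °C minus 15 °C. Equal totals shift every gene alike, by 0.17, -0.22 and -0.33 for the 3 translational efficiency counts. Restoration by hcDBP1 relative to other genes was 0.46 at 15 °C and 0.20 at 37 °C for genes chosen in the other experiment, against 0.57 and 0.60 for genes chosen in the same one, and the cause was not tested. Starting values differed, since genes chosen in ded1-cs stood at -0.49 in ded1-ts and genes chosen in ded1-ts at -1.83 in ded1-cs. The lower value at 37 °C is therefore no measure of weaker restoration there.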

Other observations

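The tests in this part were chosen after the result was seen, except that on DNA replication genes, whose prediction was written before their values were read. Gene lists named here were written after the first results, and their medians are relative to all genes.

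Histone genes stood low in ded1-ts. The 8 core histone genes had a median mRNA change of -1.69 in ded1-ts against DED1-TS, with 8 of 8 lower, and -2.18 in the double mutant against the dbp1-deletion strain, again with 8 of 8 lower. With hcDBP1 in ded1-ts they stood at 0.96 above ded1-ts, with 4 of 8 higher. HTB2, a histone H2B gene, stood at -2.22 in mRNA in ded1-ts in the authors' deposited table. Histone genes such as HTA2 have close copies whose reads may not be told apart, so the 8 values need not be independent. In ded1-cs at 15 °C the histone mRNA median was 0.02. The 31 nuclear RNA polymerase subunit genes had a median mRNA change of -0.50 in ded1-ts and -0.32 in ded1-cs, both at percentile 0 of random lists. The 33 proteasome subunit genes stood at 0.39 in mRNA in the double mutant against the dbp1-deletion strain (percentile 100), with 2 higher.

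The vacuolar proton ATPase, which acidifies the vacuole, had a median translational efficiency of -0.80 in ded1-cs (percentile 0.24), with 6 of 16 subunit genes lower and 2 higher. The lower ones included VMA5 at -2.23, VPH1 at -2.07 and STV1 at -2.32 in the authors' deposited table, while VMA10 at 1.62 and VMA9 at 1.28 stood higher in the authors' deposited table. The complex stood at 0.18 with hcDBP1 against ded1-cs (percentile 99.55) and at 0.28 in ded1-ts (percentile 97.73). Ergosterol biosynthesis genes at -0.16 and aminoacyl-tRNA synthetase genes at 0.51 lay inside the range of random lists in ded1-cs.

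Genes of the G1 to S transition stood low in ded1-ts mRNA, with CLN2 at -2.41, PCL1 at -2.39 and CLB6 at -2.30 in the authors' deposited table. A hypothesis is that fewer cells were in S phase, which would lower DNA replication genes that the naming rule did not pick. The 35 DNA replication and cohesion genes had a median mRNA change of -0.31 in ded1-ts, at percentile 0.08 of random lists, and -0.64 in the double mutant against the dbp1-deletion strain. In ded1-ts 5 of the 35 were lower and 1 higher, with POL30, the sliding clamp, at -1.57 and the cohesin subunit MCD1 at -1.62 in the authors' deposited table. The values are consistent with fewer cells in S phase, but no count of cells by phase was analysed here, and lower transcription of these genes within each cell stays open and untested.

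The genes next to DBP1 differed in the hcDBP1 strains. MRP51, its neighbour, and YPL119C-A stood higher in mRNA in both hcDBP1 strains than in their ded1 parents, the smallest of the 4 changes being 0.72, while IDI1 on 1 side and VPS30 on the other side stood at 0.16 and -0.27 at 15 °C. Neighbouring DNA carried with the high-copy gene may therefore account for the higher mRNA of MRP51 and YPL119C-A with hcDBP1, although YPL119C-A, whose footprint level lies below the minimum of 50, also stood at 1.74 in mRNA where DBP1 is deleted in the authors' deposited table. An effect of lost helicase activity on MRP51 translation stays open, since with the DBP1 locus unaltered its translational efficiency was 0.035 in ded1-ts but -1.54 in ded1-cs in the authors' deposited table, with no replicate to judge either.

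HIS3, DED1 and leucine pathway genes differed between the dbp1-deletion strain and the WT of its table. Higher Gcn4 output may contribute, since the other Gcn4 targets lay at percentile 99.97 of random lists in mRNA, with a median of 0.52. The authors' deposited table has GCN4 itself at 1.10 in translational efficiency in the dbp1-deletion strain, with footprints at 1.61 and mRNA at 0.50. The 5 Leu3 targets stood 0.83 above the other Gcn4 targets, which is consistent with altered control by Leu3, but Gcn4 targets can respond unequally, so whether Gcn4 output alone gives this difference stays open. HIS3 and DED1, which are neighbours, stood lower in both strains of that experiment, the highest of the 4 mRNA changes being -0.95, while the next genes MRM1 and GEP3 stood at 0.11 and -0.01 in the dbp1-deletion strain in the authors' deposited table. A different number of copies of the HIS3 and DED1 region in the WT cannot be told apart from a difference in regulation, because the WT matches no sample of the series.

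GCN4 translational efficiency had opposite signs in ded1-cs and ded1-ts. Scaling the columns to equal totals left the signs opposite, with GCN4 at -2.99 in ded1-cs and 1.36 in ded1-ts, a difference of 4.35. That scaling moves every gene by only -0.59 in ded1-cs and -0.07 in ded1-ts, so it does not decide on other scalings. A difference in Gcn4 output may follow, as the median mRNA difference of its target list between the mutants lay at percentile 100 of random lists. Relative to all genes, the target mRNA median was -0.32 in ded1-cs and -0.01 in ded1-ts (percentile 99.53). Against the median of all genes, the difference thus lay in lower target mRNA in ded1-cs, without a rise in ded1-ts. Against random lists of the same level, target mRNA stood low in ded1-cs (percentile 0.02) and high in ded1-ts (percentile 99.53). Temperature and allele differ together between the experiments, and none of these biological differences was tested.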
